A study of Mus musculus with 6 samples.

How the data were processed

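RNA of 6 mouse embryonic stem cell samples was measured on Illumina bead arrays, with 1 array per sample. Per the labels, 3 samples had received an shRNA vector against Chd6 (called shChd6 here) and 3 the matching control vector. Groups were taken from the labels, and every column of sample values was matched to 1 sample (0 columns were left unmatched). The labels do not say whether the 3 samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

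The deposited probe intensities are linear signals of 45281 probes, exported with GenomeStudio per the submitters' processing notes, with the version not given in the sources used here. The values themselves showed different medians on each array and a minimum between 86.0 and 99.7, so they were neither normalized between arrays nor background-subtracted. A detection p-value accompanies each signal, per the file headers, and moves in steps of 1 in 936. A second deposited table of intensities held the authors' processed values; its scale and normalization are not stated. Set against the signals, each of its columns ranked the probes as its own array did (Spearman correlation 1, against at most 0.875 with another array), and its values lay within 0.274% of a quantile normalization of the linear signals. The median of each of its 6 columns was 117.6. By this comparison its values were linear and not centred, and they served as an alternative.

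The signals were background-corrected and quantile normalized with neqc of limma 3.58.1 in R 4.3.3, with the background inferred from the detection p-values and an offset of 16, and taken to log2. Probes with a detection p-value under 0.05 on at least 3 of the 6 arrays were kept (16433 probes). GEO's platform annotation named 34885 probes by 1 gene and 18 by several, and 10378 probes are unnamed here. Symbols of 34807 probes were matched through gene identifiers to the RefSeq annotation of GRCm38.p6, which was used for names only. Of the kept probes, 14131 had 1 gene name and 2302 did not. Each gene was represented by the probe with the highest mean over the 6 arrays, which left 9463 genes, 3317 of them with more than 1 kept probe.

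Groups were compared with limma (lmFit and eBayes with a mean-variance trend), and p-values were adjusted with the Benjamini-Hochberg method. A gene counts as changed at an adjusted p under 0.05. Fold changes are shChd6 over control on the normalized scale. The offset and the background make them understate changes of dim genes. Where a probe was detected on no array of a group, the fold is given as at least N-fold: the brighter group's mean against the dimmer group's mean of, per array, the higher of the lowest signal among detected probes and the probe's own. Precision is limited by the number of arrays. Gene lists, 25 in all, were compared with the other genes by limma's camera with a preset correlation of 0.01, adjusted over the lists, and Chd6 was left out of the remodeller list. Lists with fewer than 5 measured genes were not tested. The alternative test fry asks whether a list's genes moved one way, without comparing them with other genes. Medians of lists carry bootstrap intervals (95%, 2000 draws). The same fit was tested on simulated arrays of the 9463 genes with 200 changed genes for shChd6 against control. It recovered 22 of 67 genes changed 1.5-fold, 49 of 67 changed 2-fold and 64 of 66 changed 3-fold, and 11 of its 149 calls were genes left alone. The list test found the planted list and called 0 of 24 random lists. The simulated genes varied independently, while the real lists had estimated correlations of up to 0.45. The simulation therefore does not show how often correlated lists are called falsely.

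Gene lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule took Chd6, the 12 largest rises and the 12 largest falls among changed genes whose 3 shChd6 samples lay all above or all below the 3 controls, up to 4 members of each list with the smallest p, 7 other remodellers (Chd1, Chd2, Chd4, Chd8, Chd9, Smarca4 and Ep400), and Pou5f1, Nanog, Sox2 and Zfp42. The text gives those members that bear on a list's result, and genes outside the rule are said to be so.

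The sample labels carry the letters A, B and C in both groups. Samples of the same letter deviated together from their group means over all genes (r = 0.25 for A, 0.11 for B and 0.35 for C). Every sample correlated best with its own letter, so the letters were taken to pair the samples. This check is weak. Deviations cancel within a group, so the correlations are not independent, and shChd6 replicate 2 reached r = 0.06 with control replicate 1. The pairing comes from this check of the data, since the labels do not say what a letter marks. In both groups the letters also follow the order of the arrays on the slide, so paired cultures and array position cannot be told apart as the source of the block. All 6 arrays lay on 1 slide, so the slide cannot be a block. Controls and shChd6 samples occupied separate stretches of positions on it, so position and group cannot be told apart. Alternatives covered background correction, scaling, the offset, the authors' values, the detection filter, the treatment of probes, the variance model, array weights, the replicate block, leaving out each sample and other list tests. One more, a fibroblast covariate, also combined with the other list tests, was added after seeing the data.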

Results

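The data are the expression profiles of 6 samples of mouse embryonic stem cells grown on inactivated mouse embryonic fibroblasts with 15% serum and leukemia inhibitory factor. The cells were electroporated with an shRNA vector against Chd6, a chromodomain helicase that remodels nucleosomes, or with a control vector (n = 3 each). Puromycin was applied 24 h later for 48 h, after which RNA was collected. Between 15817 and 17111 of the 45281 probes were detected per array, and shChd6 replicate 1 was the brightest array (median signal 128.8, against 110.9 to 118.9 on the others). Normalized values correlated at r = 0.978 to 0.989 within the shChd6 group, 0.985 to 0.988 within the controls and 0.971 to 0.984 between the groups.

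Chd6 itself was lower in the 3 shChd6 samples. Its detected probe (ILMN_1252290) had a log2 signal of 5.22 ± 0.25 in shChd6 and 6.19 ± 0.15 in controls (SD, n = 3 each). The samples read 5.51, 5.03 and 5.13 with the shRNA and 6.16, 6.06 and 6.35 without it. Chd6 signal was 1.95-fold lower (log2 change -0.97 ± 0.21 SE, limma, Benjamini-Hochberg adjusted p = 0.028), which left 51.2% of the control signal. An exact two-sided permutation test of Chd6 gave p = 0.1, the smallest that 3 against 3 samples allow. The Chd6 probe lay near the detection limit (highest detection p-value 0.0491), and the other 2 Chd6 probes were detected on no array. The Chd6 call was lost when any 1 sample other than shChd6 replicate 1 was left out (limma adjusted p = 0.0732 to 0.112), with median scaling (0.124) and with no detection filter (0.121). Its size depended on the background: the log2 change was -0.34 with no background correction, -0.35 in the authors' values and -0.58 with an offset of 50, with the call kept in each (limma adjusted p = 0.0302, 0.0302 and 0.0252).

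Knockdown was accompanied by changes in 247 of 9463 genes, 145 higher and 102 lower (limma, Benjamini-Hochberg), of which 240 changed at least 1.5-fold. Signal rose most for the homeobox gene En1, 5.31-fold (log2 change 2.41 ± 0.31 SE, adjusted p = 0.00295, limma). Also among the 12 largest rises, Fgf7, a fibroblast growth factor, rose 3.87-fold, the activin subunit gene Inhba 3.38-fold and the chemokine gene Cxcl1 3.15-fold. Timp2, an inhibitor of matrix metalloproteinases, rose 3.57-fold, the proteoglycan gene Dcn 3.07-fold and the complement protease gene Masp1 2.99-fold. Hes6 and Bcl11a, which encode transcriptional regulators, rose 3.23-fold and 3.14-fold, and the protease gene Ctse rose 2.87-fold. The cell adhesion gene Nrcam was detected on no control array and was at least 3.11-fold higher (limma adjusted p = 0.00182), and Cyp2b23 was at least 1.95-fold higher on the same terms (limma adjusted p = 0.00577). The mean of the embryonic fibroblast list was used as a covariate in an alternative added after seeing the data. With it 4 of the 12 rises passed (En1, Hes6, Bcl11a and Ctse, limma), and 7 had an unadjusted p under 0.05. Timp2 and Cxcl1 turned to log2 changes of -0.58 and -0.086. Dcn is itself a member of that list. The list's mean rose from letter A to C in both groups, so this fit does not sort the rises into fibroblast RNA and other sources.

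Among the 12 largest falls, the tight junction gene Cldn4 fell 2.79-fold (log2 change -1.48 ± 0.17 SE, limma adjusted p = 0.00182), the keratin genes Krt42 and Krt17 fell 2.83-fold and 2.69-fold, and Ap1m2, an adaptor subunit of epithelial sorting, fell 2.40-fold. Serpinb6c fell 3.11-fold, Mapt, which encodes tau, 2.93-fold, the adaptor gene Grb7 2.80-fold, Ano9 2.66-fold, Plac8 2.43-fold, the ligand gene Wnt7b 2.40-fold, Bdh2 2.38-fold and the histone gene H3c3 2.34-fold. Probes for Cyp2b23, Serpinb6c, the keratins and H3c3 can read near-identical relatives, so these genes are uncertain. Of 108 further kept probes of the changed genes, 105 moved in the direction of the main probe, and 27 of these passed the threshold themselves. They were read on the same arrays, so this is no independent check of the calls. With the fibroblast covariate 0 of the 12 falls passed (limma), and 12 had an unadjusted p under 0.05. Their log2 changes stayed between -2.11 (Krt42) and -0.90 (Plac8), and Cldn4 went from -1.48 ± 0.17 to -1.65 ± 0.33 SE, while the median standard error of all genes grew from 0.20 to 0.37.

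**Figure D1:**
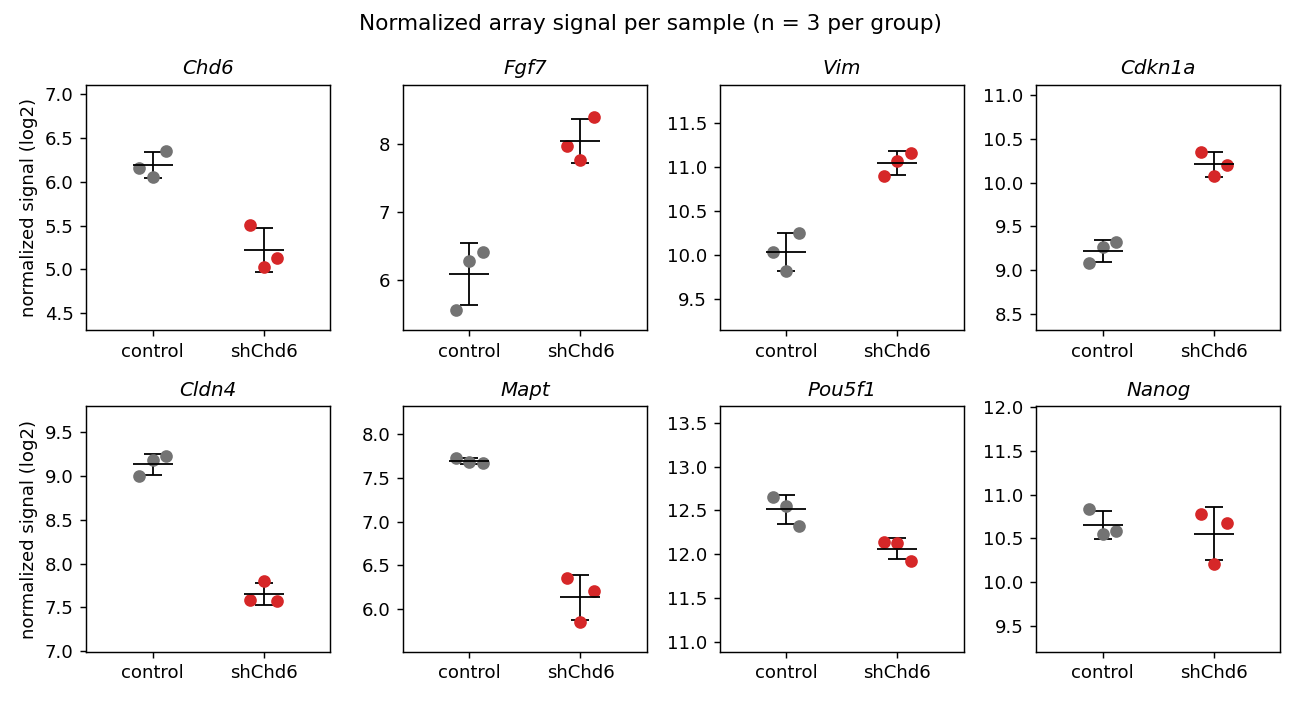
Normalized log2 signal (vertical axis) of 8 genes in the 3 control and 3 shChd6 samples; points are samples, and the horizontal line and bar give mean and SD. Chd6, Cldn4 and Mapt lay lower in every shChd6 sample, Fgf7, Vim and Cdkn1a higher, Pou5f1 was 0.45 lower and did not pass the test, and Nanog overlapped between the groups.

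The count of changed genes depended on how samples were handled. With the replicate letter as a block it was 714 (395 higher, 319 lower), which included all 247 genes; the letters also follow array position within each group. Median scaling in place of quantile normalization moved the median of all genes by 0.23 on the log2 scale. It gave 225 higher and 16 lower, so the balance of rises and falls rests on the scaling. That scaling aligned the median of all 45281 probes, of which only 34.9% to 37.8% were detected per array. Leaving out shChd6 replicate 2, control replicate 1 or control replicate 2 gave 57, 49 and 30 genes, and leaving out shChd6 replicate 1, the brightest array, gave 367. Of the 24 largest changes named above, 16 passed without shChd6 replicate 2 and 14 without control replicate 2.

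Of the 25 gene lists, 4 were higher and 3 were lower in shChd6 than the other genes (camera, adjusted p under 0.05). None of the 7 passed with an estimated correlation between genes, where the smallest adjusted p was 0.226. The fry test, which asks whether a list's genes moved one way and not whether they differed from other genes, did not call the fibroblast, neuroectoderm, cholesterol and histone lists (adjusted p = 0.0889, 0.0576, 0.181 and 0.32). With no background correction the medians given below shrank to 0.41 for fibroblast, 0.17 for p53, 0.17 for Polycomb and -0.16 for cholesterol genes. A list's call with the preset correlation is a weak one here, since another split of the 6 samples called 6 lists.

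Embryonic fibroblast genes, fixed because such cells were the feeder layer, had the largest shift. The median of the 17 measured genes was 1.01 higher on the log2 scale (camera adjusted p = 8.64e-09; adjusted p = 0.333 with an estimated correlation). Of these, 7 rose and 0 fell over all genes, and 12 rose and 1 fell adjusted over the list alone. Dcn, the intermediate filament gene Vim (2.02-fold), the metalloproteinase inhibitor gene Timp1 (2.06-fold) and the chemokine gene Ccl2 (2.20-fold) were among the 7. With the replicate block 11 rose and 1 fell. The members below 0, Thy1 and Fn1, were chosen after their values were seen. Thy1 had a log2 change of -0.65 ± 0.25 SE (limma adjusted p = 0.207) and was the 1 that fell over the list alone and with the block (limma adjusted p = 0.029), and Fn1 had a log2 change of -0.02. The list's mean differed between samples of one group too, from -0.80 in control replicate 1 to -0.10 in control replicate 3 relative to the mean of all samples, against 0.26 to 0.59 in shChd6. Every shChd6 sample lay above every control for this mean. The same held for the means of the p53, Polycomb and neuroectoderm lists and, with the groups exchanged, the naive pluripotency list. The cholesterol and histone means overlapped between the groups. Among lists that were not called, the Nrf2 and immediate early means were separated upward and the trophoblast mean downward. Separation was thus not particular to the called lists. With the fibroblast mean as a covariate, the Polycomb, neuroectoderm, naive pluripotency, cholesterol and histone lists were not called (camera adjusted p = 0.239, 0.203, 0.434, 0.592 and 0.0559). That mean rose from letter A to C in both groups, so the lost calls cannot be laid to fibroblast RNA alone.

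Targets of the tumour suppressor p53 were higher as a list, with 19 of 24 measured targets above 0 and 5 below. Of the 24, 6 rose and 0 fell over all genes, 8 rose adjusted over the list alone and 9 with the replicate block (median 0.29 on the log2 scale, camera adjusted p = 4.39e-05; adjusted p = 0.226 with an estimated correlation). Cdkn1a, the cell cycle inhibitor p21, rose 1.98-fold (log2 change 0.98 ± 0.15 SE, limma adjusted p = 0.00691). The cyclin gene Ccng1 rose 1.92-fold, the Akt inhibitor gene Phlda3 1.83-fold and Mdm2, which encodes the ligase that degrades p53, 1.51-fold. In shChd6 replicates 1, 2 and 3 the list's mean was 0.25, 0.17 and 0.11 relative to the mean of all samples, where the fibroblast mean was 0.26, 0.32 and 0.59. In control replicates 1, 2 and 3 the p53 mean was -0.15, -0.23 and -0.14, where the fibroblast mean was -0.80, -0.27 and -0.10. The opposite order of the 2 means in shChd6 was thus not seen in the controls.

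Of 36 listed developmental genes that Polycomb complexes repress in stem cells, 8 were measured, and of these 3 rose over all genes and 4 adjusted over the list alone, with a median of 0.51 (camera adjusted p = 0.00164; adjusted p = 0.226 with an estimated correlation). The detection filter favours rises here, since a gene silent in controls enters only if it is detected in shChd6. Wnt5a and Hoxa5 were detected on 3 shChd6 and 0 control arrays. Hoxa5 was at least 1.16-fold higher and did not pass (limma adjusted p = 0.0874). Wnt5a was at least 1.95-fold higher, Sox9 rose 2.07-fold and Irx3 1.87-fold. Among 7 neuroectoderm genes the median was 0.41 (camera adjusted p = 0.0122; adjusted p = 0.267 with an estimated correlation), and Sox21, a neural progenitor factor, rose 1.83-fold as the single change over all genes and over the list alone. Leaving out shChd6 replicate 1 or 3 left 4 measured Polycomb genes, too few for a test, and without shChd6 replicate 2 the list was not called (camera adjusted p = 0.0535), nor was the neuroectoderm list without shChd6 replicate 1 (camera adjusted p = 0.0663) or with array weights (camera adjusted p = 0.0542). With no detection filter neither was called (camera adjusted p = 0.218 for Polycomb and 0.304 for neuroectoderm).

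Naive pluripotency genes were lower as a list (median log2 change -0.17), a direction that turned under median scaling (median 0.07) unless the shift of all genes was taken off (-0.15). Over all genes 1 of 26 measured members fell and 0 rose, 5 fell adjusted over the list alone and 5 with the replicate block (camera adjusted p = 0.00958; adjusted p = 0.226 with an estimated correlation). Tfcp2l1, a naive state transcription factor, fell 1.69-fold (limma adjusted p = 0.0298). Pou5f1, which encodes Oct4, had a log2 change of -0.45 ± 0.12 SE that missed the threshold (limma adjusted p = 0.0763) and passed it with the replicate block (limma adjusted p = 0.0146). Tcl1 (log2 change -1.02) and Dppa3 (log2 change -0.85) behaved alike, with limma adjusted p of 0.0606 and 0.0695, and 0.00126 and 0.00569 with the block. Nanog, Sox2 and Zfp42 had log2 changes of -0.10, -0.08 and -0.30 and did not pass in either fit.

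Cholesterol synthesis genes had a median log2 change of -0.29 over 16 genes, -0.06 under median scaling and -0.28 with the shift of all genes taken off (camera adjusted p = 0.00365; adjusted p = 0.389 with an estimated correlation), and Fdps, which makes farnesyl diphosphate, fell 1.61-fold as the single change over all genes and over the list alone. Replication-dependent histone genes had a median of -0.31 over 33 genes, -0.15 under median scaling and -0.36 with the shift taken off (camera adjusted p = 0.00164; adjusted p = 0.652 with an estimated correlation), with 5 lower and 1 higher over all genes, 11 lower and 2 higher adjusted over the list alone, and 8 lower and 2 higher with the replicate block. The H3 genes H3c6, H3c1 and H3c4 fell 1.79-fold, 1.85-fold and 1.78-fold and the linker histone gene H1f2 rose 1.86-fold, with probes that can read near-identical copies. The histone list was not called without shChd6 replicate 1 (camera adjusted p = 0.129).

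**Figure D2:**
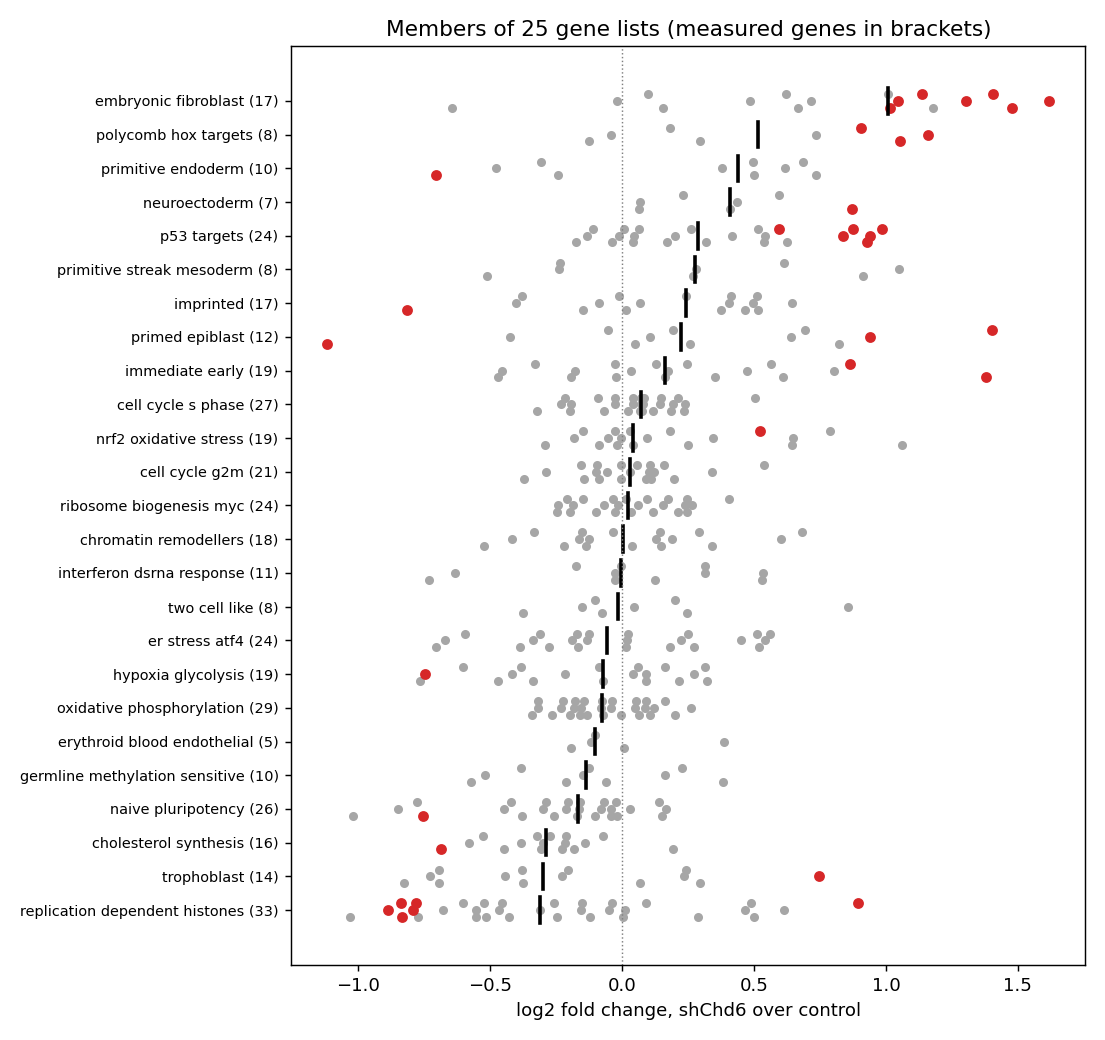
Log2 fold change of shChd6 over control (horizontal axis) for the measured members of 25 gene lists; each point is a gene, red points passed an adjusted p of 0.05 over all genes, and black bars are list medians. The fibroblast list lay farthest right, with a median of 1.01, and the histone list farthest left, with a median of -0.31.

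The other 18 lists were not called. Chromatin remodellers, the family of Chd6, had a median of 0.00 over 18 genes with 0 changed (camera adjusted p = 0.9). The related Chd1, Chd2, Chd4, Chd8 and Chd9 had log2 changes of 0.60, 0.19, -0.03, 0.13 and -0.13, and Smarca4 and Ep400 of -0.33 and -0.16. None passed (limma), although Chd1 and Smarca2 (log2 change 0.68) did with the replicate block (limma adjusted p = 0.0227 and 0.0409). Primed epiblast genes held both directions: Zic2 rose 2.64-fold, Fgf5 was at least 1.80-fold higher and the claudin gene Cldn6 fell 2.17-fold (camera adjusted p = 0.0638, and 0.024 with the replicate block). The Fgf5 call was lost in 9 of 14 alternatives, among them no background correction, the authors' values and leaving out any control sample. The primed list was also called without shChd6 replicate 3 (0.0458), without control replicate 1 (0.0242) and with the fibroblast covariate (0.000875; adjusted p = 0.52 with that covariate and an estimated correlation). The streak and mesoderm list was called without control replicate 3 (camera adjusted p = 0.0429), the trophoblast list with median scaling (0.0314) and the germline list with each probe on its own (0.034). In the main setting these lists and the primed list had adjusted p = 0.66, 0.443, 0.68 and 0.427 with an estimated correlation. Among lineage lists, primitive endoderm had a camera adjusted p of 0.312 with Lama1 falling 1.63-fold, trophoblast 0.243 with Fgfr2 rising 1.68-fold, and primitive streak and mesoderm 0.243 with 0 changed over all genes. Genes of the 2-cell-like state had a camera adjusted p of 0.709, germline genes sensitive to methylation 0.38, and blood and endothelial genes 0.953, each with 0 changed. Imprinted genes had 0.255, with Phlda2, a placental growth inhibitor, falling 1.76-fold. With the replicate block 5 primed genes rose and 1 fell, 1 trophoblast gene rose and 3 fell, 3 imprinted genes rose and 1 fell, 1 primitive endoderm gene rose and 1 fell, and 2 streak and mesoderm genes and 1 gene of the 2-cell-like state rose (limma).

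Immediate early genes had a camera adjusted p of 0.11, with Ccn1 rising 2.60-fold and Ccn2 1.82-fold. The Nrf2 oxidative stress list had 0.124, with the ferritin gene Fth1 rising 1.44-fold, and hypoxia and glycolysis genes 0.243, with Pfkp falling 1.68-fold. Immediate early genes were called without control replicate 1 (camera adjusted p = 0.04), with each probe on its own (camera adjusted p = 0.00575) and by fry (adjusted p = 0.0139). The Nrf2 list was called with each probe on its own (camera adjusted p = 0.0197), and hypoxia and glycolysis genes without control replicate 2 (camera adjusted p = 0.0342). With an estimated correlation in the main setting the immediate early, Nrf2 and hypoxia lists had adjusted p = 0.371, 0.389 and 0.66. Interferon and double-stranded RNA response genes had 0 of 11 changed (median 0.00, camera adjusted p = 0.68). Genes of ER stress, oxidative phosphorylation, S phase, G2 and M phase, and ribosome biogenesis had 0 changed, with camera adjusted p of 0.9, 0.314, 0.697, 0.709 and 0.709. These counts are those without the replicate block. With it 5 immediate early and 5 Nrf2 genes rose, 3 hypoxia and glycolysis genes fell, 1 ER stress gene rose and 3 fell, and 1 G2 and M phase gene rose (limma).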

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

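The fibroblast covariate was chosen after seeing the data. The cause of each difference below was not tested, except that leaving out samples and adding a covariate leave fewer degrees of freedom. The 6 samples make 10 splits into 3 and 3, too few for a share under 0.05: 1 of the 10, the real one, gave 247 genes, and the highest other gave 0. With the replicate block, 1 of the 4 splits that part all 3 pairs gave 714 genes, and the highest other gave 0. For gene lists, the real split called 7 and the highest other called 6. Genes changed, higher, lower and changed at least 1.5-fold numbered 124, 71, 53 and 124 with no detection filter, 147, 89, 58 and 147 without a variance trend, 484, 271, 213 and 420 with array weights, 714, 395, 319 and 576 with the replicate block, and 13, 8, 5 and 13 with the fibroblast covariate. Median scaling gave 225 higher and 16 lower, and the strict filter gave 83 higher. At least 1.5-fold changes numbered 139 with no background correction and 142 in the authors' values, where background compresses folds. Leaving out 1 sample gave 30 to 367 genes, 19 to 205 higher, 11 to 162 lower, 30 to 314 at least 1.5-fold, 14 to 22 of the 24 largest changes and 4 to 9 lists. With the covariate 4 of those 24 changes and 2 lists passed, and Timp2, Cxcl1 and Fbln2 (a gene outside the fixed rule, chosen after its values were seen) turned to -0.58, -0.086 and -0.37. Lists called numbered 0 with an estimated correlation and 4 with fry. Chd6 stayed lower in all 17 alternatives (log2 change -1.06 to -0.34) and passed in 9. It missed the threshold at -0.76 with median scaling, -0.97 with no filter and -0.97 with the covariate, and lay between -1.06 and -0.88 with 1 sample left out. The strict filter removed its probe. The replicate block called 1 more list and 25 more named genes and ended no call. The p53 list passed in 20 of 21 alternatives, the naive pluripotency list in 19, the fibroblast and cholesterol lists in 18, the histone list in 17, the neuroectoderm list in 15 of 21 and the Polycomb list in 14 of 18. The fibroblast list's loss with the covariate was fixed in advance, since the covariate was that list's own mean. Without shChd6 replicate 1 or 3 the Polycomb list had 4 measured genes, and with the strict filter Polycomb, streak and mesoderm, and blood and endothelial genes had 2, 3 and 2, under the minimum of 5 for a test. Lists called in alternatives but not in the main setting were immediate early genes, Nrf2, germline, trophoblast, primed epiblast, streak and mesoderm, and hypoxia genes. Genes near background, such as Chd6, are limited by signal over background. Among values that passed in neither setting, 62 changed sign.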

Other observations

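The tests in this part of the fibroblast, p53 and fallen genes were chosen after the result was seen, except the test of a second fibroblast list; the gene lists for that test, for epithelial genes and for BMP targets were written before their values were seen. Genes named here outside the fixed rule were chosen after their values were seen.

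Epithelial genes other than Cldn4, Cldn6 and Ap1m2 were lower as a list, which took in regulators, proteases and junction genes. Of the 17 measured, 14 had a negative log2 change, with a median of -0.40, or -0.24 under median scaling and -0.16 with no background correction (camera p = 4.3e-06, and p = 0.00775 with an estimated correlation). The transcription factor gene Elf3 fell by 0.97 on the log2 scale (limma adjusted p = 0.0358) as the single one past the threshold. The splicing regulator gene Esrp1 had a log2 change of -1.03, Rab25 of -0.92 and the E-cadherin gene Cdh1 of -0.56, with limma adjusted p of 0.0527, 0.0624 and 0.111. No junction gene of the list passed, and the 3 members above 0, Cldn7, Tjp3 and Cdh3 (log2 change 0.21, 0.03 and 0.03), are junction genes. These values go with a shift of epithelial genes as a group, a hypothesis for these cells. Fibroblast genes rose in the same samples (median 1.01), and this list was not tested with the fibroblast covariate.

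Id1 and Id2, inhibitors of helix-loop-helix factors and targets of BMP signalling, rose 1.86-fold and 2.84-fold. Among 5 other measured BMP targets Grem1 and Id3 rose by 1.28 and 0.89 on the log2 scale (limma adjusted p = 0.0362 and 0.0453), and the list had a camera p of 0.0168, but p = 0.202 with an estimated correlation. The list's median was 0.63, and 0.20 with no background correction. It was not tested as a list with the fibroblast covariate, although fibroblast genes rose in the same samples (median 1.01). With the fibroblast covariate the Id1 and Id2 calls were lost (limma adjusted p = 0.174 and 0.137), at log2 changes of 0.89 ± 0.15 SE before and 1.00 ± 0.30 after for Id1, and 1.51 ± 0.27 and 1.82 ± 0.50 for Id2. A rise of BMP targets as a group may be followed up on that footing. Among the 2302 kept probes without a gene name, 33 passed an adjusted p of 0.05 (limma), 17 higher and 16 lower.

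The rise of fibroblast genes could come from more feeder RNA in the shChd6 samples or from the stem cells themselves. A second list of 27 measured fibroblast matrix and cytoskeleton genes was higher too (median 0.60, camera p = 5.2e-10, p = 0.0822 with an estimated correlation). Its median was 0.28 with no background correction and 0.78 under median scaling. The first list's members deviated together within the groups (mean correlation 0.39, percentile 100 among 1000 random lists). A varying amount of fibroblast-like RNA would give this. The histone list had a higher mean correlation of 0.45, however, so such RNA is not singled out. More feeder RNA could bring the 5 abundant fibroblast genes Col1a1, Col1a2, Col3a1, Postn and Lum to detection on all shChd6 arrays. Of these, 0 were, which decides nothing without knowing what the feeder cells expressed. A probe each of Col1a1 and Lum was detected on 2 shChd6 arrays and 0 control arrays. The first list's matrix genes Bgn, Lox and Col5a1 were detected on every array. They were brighter in shChd6 (mean log2 signal 11.37, 7.89 and 9.08) than in controls (9.89, 6.48 and 8.07). Of the first list's 17 measured members, 15 lay above 0 and 2 below. Thy1 was among those below (log2 change -0.65 ± 0.25 SE, limma adjusted p = 0.207, and 0.029 with the replicate block). All samples had 48 h of puromycin, and since whether the feeder cells resisted it, what they expressed and whether these probes respond cannot be read from the labels or arrays, feeder RNA and a change in the stem cells cannot be told apart for this list. Hprt rose 2.64-fold, which would bear on it only if the stem cells lacked Hprt, and the labels do not name the line.

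If the p53 list's shift came from the fibroblasts whose markers rose, it should shrink toward 0 with their mean as a covariate. It did not shrink, but this does not decide the question. The fibroblast mean rose from letter A to C in both groups (shChd6 0.26, 0.32 and 0.59, controls -0.80, -0.27 and -0.10). The covariate therefore cannot part fibroblast RNA from letter or array position, and fibroblast RNA stays open. With the mean of the fibroblast list as a covariate, the median group coefficient of the 24 targets was 0.54 (interval over genes 0.18 to 0.79), against 0.29 without it, and 5 of the 6 single changes had an interval above 0 (limma). The list passed by camera with the preset correlation (adjusted p = 0.000875) but not with an estimated one (p = 0.0585, adjusted p = 0.52, against an adjusted p of 0.226 without the covariate), and fry gave p = 0.0165 (adjusted p = 0.266). None of the 6 single calls held (0 of 6, limma): Cdkn1a went from 0.98 ± 0.15 to 0.79 ± 0.30 mainly as its standard error grew, while for Fas the estimate itself dropped, from 0.93 ± 0.22 to 0.38 ± 0.40. An interferon response to the hairpin stays open, since the interferon list's median of 0.00 had an interval that reached 0.31, as do a response of the stem cells to losing Chd6 and one to this hairpin, since the labels name no second hairpin against Chd6.

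Dilution of stem cell RNA by RNA of other cells would lower all stem cell genes alike, and it stays open for the fallen genes. Because genes called as falls lie low by their selection, 102 falls were chosen without 1 shChd6 and 1 control sample and measured between those 2 samples. Over the 9 choices of the samples left out, the median of the chosen genes lay between -0.80 and -0.48 and that of the naive pluripotency list between -0.27 and -0.09. The intervals of both medians were apart in 8 of the 9, among them the 3 choices of the same letter (gaps of 0.14 for A, 0.12 for B and 0.40 for C), and overlapped for shChd6 replicate 3 with control replicate 1 (gap -0.072). These values lean against dilution as the whole cause, but the bound set before this test asked for all 9 choices, so neither dilution nor a change in the cells is excluded.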
